A study of Mus musculus with 8 samples.

How the data were processed

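Total RNA of mouse hippocampus was labelled with Cy3 from 0.1 µg per sample and hybridised to 8 arrays, 1 per mouse label, per the labels' protocols. Per the file headers, the images were quantified with Agilent Feature Extraction 10.10.1.1, and the probes had been designed on the mouse build mm9. The deposited values are linear intensities per spot: a processed signal, corrected by that software for background and not normalized between arrays, and the median brightness of each spot and of its local background, with flags for outliers, saturation and signal well above background. All 8 arrays were on 1 slide and in 1 scan, so that slide and scan could not be fitted as batches. Replicates 1 and 2 of both groups lay in one row of the slide and replicates 3 and 4 in the other, while slide columns 1 and 3 held wild-type and columns 2 and 4 Ts1Cje arrays, so that column and genotype cannot be told apart.

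Control spots and spots carrying an outlier flag were left out, and no spot was saturated. The log2 of the processed signal was averaged over the spots of a probe, and the 75th percentile of each array over its 55681 non-control probes was subtracted. Probes well above background on all 4 arrays of at least 1 group were kept (32596). Probes were named through their RefSeq accession in a reference table of assembly GRCm38.p6, which matched 27235 probes to 20660 symbols. Another 16194 probes are mm9 intervals and 12252 have neither, and these keep the design's name. Because the builds differ, the table served for names, chromosomes and gene order only, and coordinates are not printed. Each gene is represented by its brightest kept probe; for Dop1b, Lgals3bp, Itsn1 and Sp8 the values of other probes above background on all 8 arrays are also given. Features without a RefSeq name could not be placed in or out of the segments unless their interval lies on another chromosome than 12 or 16; 238 intervals on those chromosomes and 6048 other features are in no segment.

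Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no block), and genes with a Benjamini-Hochberg adjusted p under 0.05 over all features were called. Intervals are the moderated 95% intervals of that fit. Gene lists were compared as the mean over members per array with a two-sided exact permutation test over the 70 assignments, and with camera (preset correlation 0.01 and estimated correlation) and fry, adjusted over the 30 lists other than the 2 segments. Members of the segments are in no other list. P-values measure the spread between the labelled replicates, taken as separate mice.

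Named genes were fixed by a rule before the data were examined: Sod1, App, Dyrk1a, Rcan1, Olig1, Olig2, Kcnj6, Ifnar1, Ifnar2, Erg and Tbx1 whatever their values; the 8 triplicated genes with the largest fold among those past the threshold whose groups do not overlap; every member of the deleted segment; outside both segments up to 10 such genes per direction, leaving unnamed models and further members of a multigene family unnamed; and of every other list up to 2 members past the threshold or, where the list passed with camera, its 2 smallest p. Genes named outside this rule were chosen after their values were seen, and the text says so where it singles them out.

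The fit was tested on simulated data with the means and spreads of the 24025 features, 200 of them changed. It recovered 65.0% of those changed 1.5-fold and 90.0% of those changed 2-fold, with 7 false calls among 162. With no change it made 0 calls. Every simulated value was drawn independently, without correlation between genes or between arrays, so these rates may not hold for the real arrays. Alternatives fixed beforehand were normexp (offset 50), quantile normalization, the array median as centre, other probe filters, other rules for the probes of a gene, array weights, a trended and robust variance prior, the replicate number as a block, other thresholds, other definitions of the lists, and each array left out in turn. Feature Extraction's mean signal was not in the columns used here, so normexp ran on the median signals. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15, which also read the files with pandas 2.3.3.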

Results

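Hippocampal RNA from 3-month-old mice was measured on 8 one-colour expression arrays, 4 from Ts1Cje mice and 4 from wild-type mice, all C57BL6/J per the labels. Ts1Cje is a mouse model of Down syndrome. It carries an extra copy of the distal part of mouse chromosome 16, from Sod1 to Zbtb21, with 1 copy of Sod1 disrupted, and the translocation that holds this extra copy has removed the distal end of 1 chromosome 12. The arrays came as 4 pairs of Ts1Cje mice and wild-type littermates, per the series' description, and each label names a separate replicate. Between 59.9% and 63.1% of the 55681 probes were well above background on each array, and Pearson's r across genes between any 2 arrays lay between 0.992 and 0.996, where genes are not independent replicates. After the filter, 24025 features were tested, of which 15089 were named genes. The number of arrays limits the precision of every value.

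The first question was which transcripts differ between Ts1Cje and wild-type hippocampus, and where in the genome they lie. Genes of the triplicated segment were the largest group of calls: 26 of the 64 tested named genes annotated from Sod1 to the end of chromosome 16 were higher in Ts1Cje, and none of the 64 was lower past the threshold. Of all 24025 features, 42 were higher and 5 were lower (limma, Benjamini-Hochberg adjusted p under 0.05), and 2097 had an unadjusted p under 0.05. Beyond the triplicated segment, the calls were Dnah11 in the deleted chromosome 12 segment, 9 features outside both segments, and 11 features with no position here, all 11 higher. Chromosome 16 held 27 of the called named genes, more than its share of the tested genes (two-sided Fisher's exact p = 2.0e-34, adjusted over chromosomes 4.2e-33), and no other chromosome passed that test. The arrays of the groups did not overlap for 1470 features, 6.12% against 2.86% by chance. Quantile normalization gave 47 higher and 13 lower, so that 78.3% of its calls were higher against 89.4% in the main setting. The triplicated segment held 26 of the 47 calls, 28 of 60 with quantile normalization, 27 of 58 with the mean over probes, 28 of 59 with probes above background on all 8 arrays and 35 of 89 with array weights. The total was 23 with no filter on dim probes, 25 with the array median as centre, 71 with a trended and robust variance prior and 89 with array weights. With the replicate number as a block it was 1, with 0 in the triplicated segment and 0 outside both segments. The labels do not say that equal numbers mark a pair of littermates. Leaving out 1 array moved the total of 47 to 13 without Ts1Cje replicate 4, 19 without Ts1Cje replicate 2, 24 without wild-type replicate 4, 25 without Ts1Cje replicate 3 and 28 without wild-type replicate 2.

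**Figure D1:**
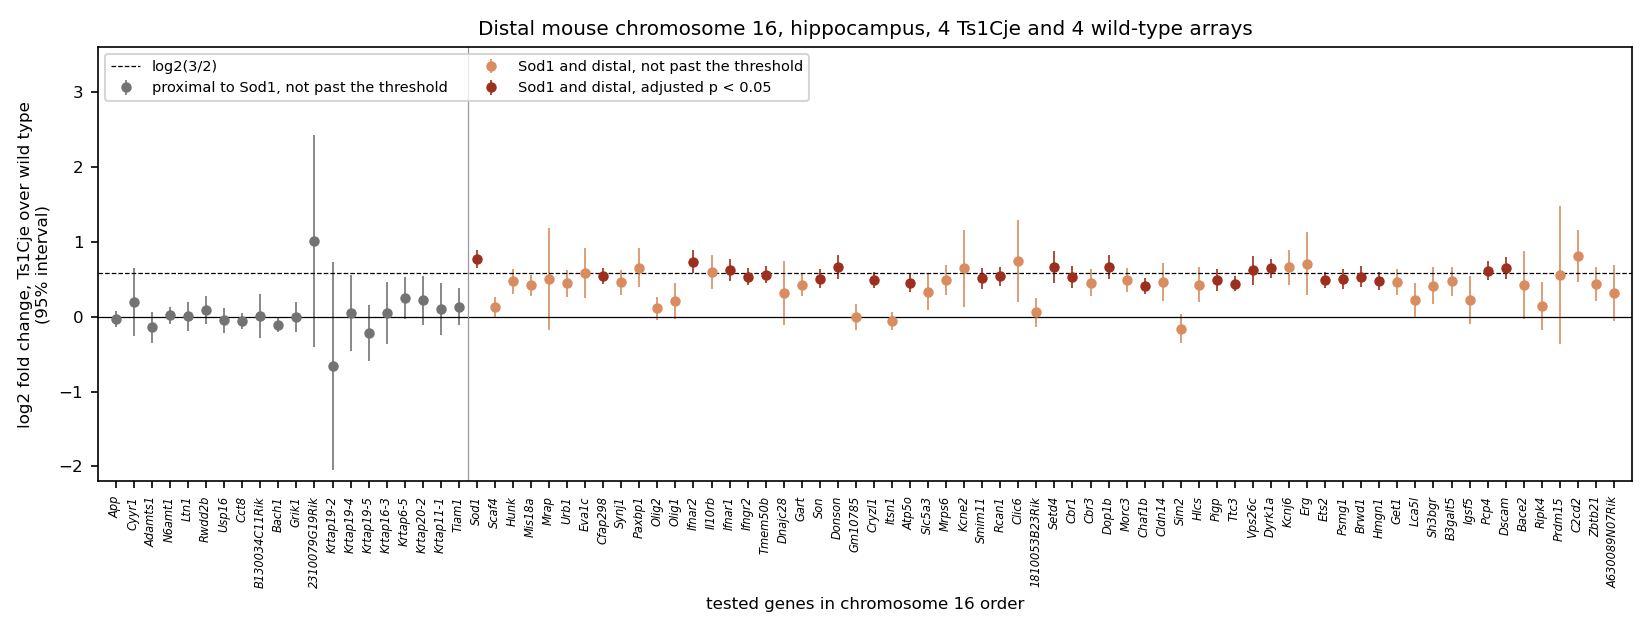
Log2 fold change of Ts1Cje over wild type (y axis) with its 95% interval for the tested named genes of distal chromosome 16, in chromosomal order (x axis), from 4 arrays per group; the vertical line marks the proximal side of Sod1 and the dashed line is the log2 of 3 copies over 2, 0.58. The 20 genes proximal to Sod1 have a median of 0.01 and none is called, whereas 61 of the 64 genes from Sod1 on lie above 0.

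The rise was seen from Sod1 on, though Scaf4, the next tested gene, had a log2 fold change of 0.12. The 20 tested genes proximal to Sod1 had a median log2 fold change of 0.01 with none past the threshold. They ranged from -0.66 to 1.01, with an SE of 0.61 at both ends. The nearest of them, Tiam1, stood at 0.13, and App, the amyloid precursor protein gene, stood at -0.03 (SE 0.05, adjusted p = 0.86). Sod1, which encodes copper-zinc superoxide dismutase, was 1.71-fold higher (log2 7.11 ± 0.06 against 6.34 ± 0.05 relative to the 75th percentile of the array, SD, n = 4 each; limma adjusted p = 0.0032). One of its 3 copies is disrupted, and the probe's place relative to that disruption was not determined here, so the value does not check the labels' copy number. Among the list of triplicated genes fixed without Sod1, 58 of 60 tested members were higher and 25 passed over all genes, or 48 adjusted over the list alone. The mean over its members was 0.48 higher on the log2 scale in Ts1Cje, with differences between single arrays of 0.45 to 0.54, so that all 4 Ts1Cje arrays lay above all 4 wild-type arrays (two-sided exact permutation p = 0.0286, the smallest the 70 assignments can give). The list stood apart from other genes with a preset correlation (camera p = 3.5e-70) and with an estimated correlation (p = 1.0e-06).

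The median fold of the 60 members was 1.40, against 1.5 for 3 copies over 2. The largest changes past the threshold with groups that did not overlap were, after Sod1, Ifnar2 (1.66-fold), Setd4 (1.59-fold), Dop1b (1.59-fold), Donson (1.59-fold), Dyrk1a (1.56-fold), Dscam (1.56-fold) and Ifnar1 (1.54-fold), with adjusted p between 0.0078 and 0.0470. The other probe of Dop1b gave 2.14-fold. Ifnar1 and Ifnar2 encode the chains of the type I interferon receptor, Dyrk1a encodes a protein kinase, and Dscam a neuronal adhesion molecule. Dyrk1a stood at 0.42 ± 0.05 in Ts1Cje and -0.22 ± 0.08 in wild type (log2, SD, n = 4 each). Rcan1, a regulator of calcineurin, was 1.45-fold higher (adjusted p = 0.0105). Kcnj6, a potassium channel subunit, stood at 0.66 (SE 0.10, adjusted p = 0.066) and Erg, an endothelial transcription factor, at 0.71 (SE 0.18, adjusted p = 0.34). Sod1, Ifnar2 and Dyrk1a passed without each of the 8 arrays in turn, whereas Setd4 passed in none of those 8 settings. Donson and Rcan1 each lost their call without Ts1Cje replicates 2, 3 or 4 or wild-type replicate 4, Dop1b without Ts1Cje replicates 2, 3 or 4, Ifnar1 without Ts1Cje replicates 2 or 4, and Dscam without Ts1Cje replicate 4.

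The 95% intervals of 46 of the 60 members held the log2 of 3 over 2, those of 6 lay below it and above 0, and none lay above it. The interval of Sod1, which is not in this list, was 0.66 to 0.89 and lay above it. Another 8 members held 0 and excluded the 3-copy ratio. These 8, named because of their intervals after the values were seen, were Lca5l, Scaf4, Sim2, Igsf5, Itsn1, Ripk4 and the oligodendrocyte transcription factors Olig1 (0.21, SE 0.10) and Olig2 (0.11, SE 0.07). For Itsn1, which encodes an endocytic scaffold protein, the probes disagreed: the brightest gave -0.06, and the 5 other probes above background on all 8 arrays gave 0.38 to 0.57. The probes of Sim2 also disagreed. Its brightest gave -0.16 and its other kept probe 0.66, the latter above background on 4 Ts1Cje arrays and 1 wild-type array.

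The second question concerned the deleted end of chromosome 12, which leaves 1 copy. Its members did not move together. Dnah11, a dynein heavy chain gene of motile cilia, was 125-fold higher in Ts1Cje (log2 3.42 ± 0.06 against -3.54 ± 0.37, SD, n = 4 each; limma adjusted p = 2.0e-06), on its 1 probe, which was above background on all 8 arrays, and it passed without each array in turn. Across 20 alternative settings its log2 fold change ranged from 5.78 to 7.09. Itgb8, an integrin subunit, stood at -1.11 (SE 0.16, adjusted p = 0.055), Tmem196 at -1.02 (SE 0.15, adjusted p = 0.057) and the transcription factor Sp4 at -0.56 (SE 0.10, adjusted p = 0.10). These 3 passed adjusted over the list alone, and their arrays did not overlap between groups. The 1-copy ratio is -1 on the log2 scale. The 95% intervals of Itgb8 (-1.49 to -0.73) and Tmem196 (-1.37 to -0.67) held it. Those of Sp4 (-0.78 to -0.33) and Sp8 (-0.21 to 0.19) lay above it. Over the alternative settings Itgb8 ranged from -1.28 to -0.64, Tmem196 from -1.15 to -0.52 and Sp4 from -0.61 to -0.46. Sp8 stood at -0.01 (SE 0.09), or -0.23 (SE 0.13) on its other probe. Macc1 and Abcb5 were not well above background on all arrays of either group and were not tested. The list's median was -0.56 and camera put it lower (p = 0.10, and 0.15 with an estimated correlation), whereas its mean was 0.85 higher (exact permutation p = 0.0286), and without Dnah11 the mean was -0.67. Proximal to Dnah11, 20 genes of chromosome 12 had a median of -0.01, and Rapgef5, the nearest, stood at -0.02.

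**Figure D2:**
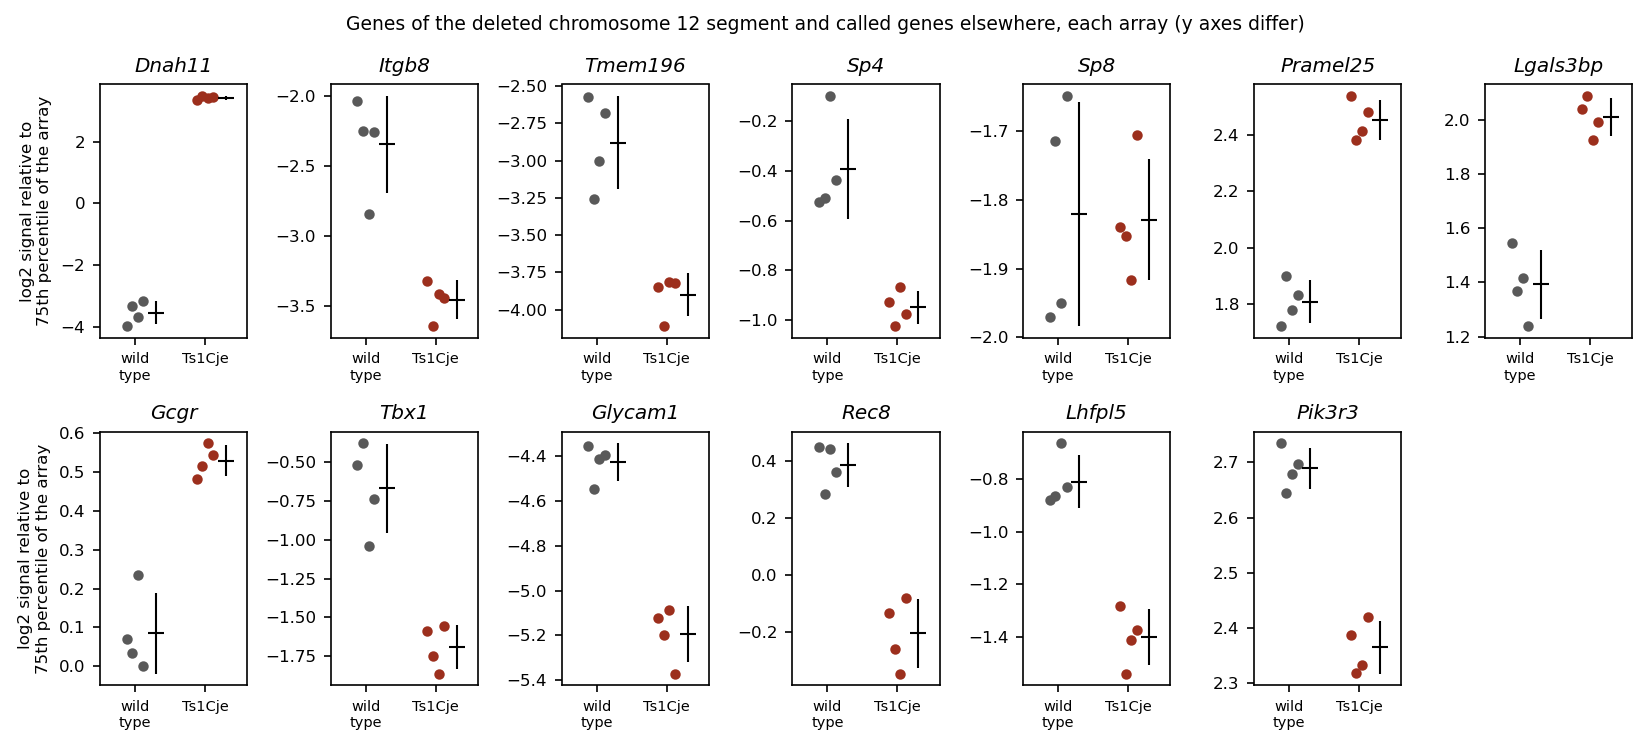
Normalized log2 signal relative to the array's 75th percentile (y axis, scaled per gene) of each wild-type and Ts1Cje array (points, n = 4 each) for tested genes of the deleted chromosome 12 segment and for named genes called elsewhere; bars show the mean and SD. Dnah11 stands at 3.42 in Ts1Cje and -3.54 in wild type, Sp8 overlaps between groups, and the arrays of the other genes shown do not overlap.

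Outside both segments, 9 of 17670 features passed, 4 higher and 5 lower, and 1472 had an unadjusted p under 0.05. The named genes that were higher were Pramel25, of the Prame-like family (1.56-fold, adjusted p = 0.0078), Lgals3bp, a secreted galectin-binding glycoprotein (1.53-fold, or 1.35-fold on its other probe, adjusted p = 0.019), and the glucagon receptor gene Gcgr (1.36-fold, adjusted p = 0.044). The fourth was an unnamed interval on chromosome 6. Those that were lower were Tbx1, a T-box transcription factor gene on chromosome 16 proximal to the segment (0.49-fold, log2 -1.69 ± 0.14 against -0.67 ± 0.29, SD, n = 4 each; adjusted p = 0.048), Glycam1 (0.59-fold, adjusted p = 0.0085), the meiotic cohesin gene Rec8 (0.67-fold, adjusted p = 0.022), Lhfpl5 (0.66-fold, adjusted p = 0.022) and Pik3r3, a regulatory subunit of phosphoinositide 3-kinase (0.80-fold, adjusted p = 0.049). Glycam1 was above background on 1 of 4 Ts1Cje arrays, so that its fold is uncertain, and its call was lost with normexp (-0.22, adjusted p = 0.32), with the trended and robust prior (0.12) and without Ts1Cje replicate 2 (0.052). Pramel25 belongs to a multigene family, so that its signal may include related transcripts, and its other probe was not above background. Adjusted over the outside features alone, Pramel25, the chromosome 6 interval and Glycam1 passed. The count of 9 was 3 with no filter on dim probes, 4 with the array median as centre, 15 with probes above background on all 8 arrays, 16 with normexp, 17 with quantile normalization, 18 with the mean over probes, 19 with the trended and robust prior and 28 with array weights. With the replicate number as a block it was 0. It was 1 without Ts1Cje replicate 4, 2 without Ts1Cje replicate 2, 3 without wild-type replicate 2 and without wild-type replicate 4, and 4 without Ts1Cje replicate 3. Pik3r3 and Rec8 passed in none of the 8 settings that leave out an array, and Tbx1, Gcgr and Lgals3bp passed in 1 each.

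Groups of genes that stand for cell types, brain regions and pathways, fixed before the data were examined, showed small shifts, and no member of the 30 lists passed over all genes. Interferon-response genes stood higher as a group: 29 of 32 were above 0, 10 had an unadjusted p under 0.05, none passed adjusted over the list alone, and the median was 0.19. Usp18, a negative regulator of interferon signalling, stood at 0.49 (SE 0.12, adjusted p = 0.32) and Ifi27 at 0.22 (SE 0.06, adjusted p = 0.34). The list passed with camera's preset correlation (adjusted p = 3.0e-08) and not with an estimated correlation (adjusted p = 0.63). Unadjusted, camera's p with the preset correlation was 1.0e-09 between the genotypes. Groupings of the 8 arrays that mix genotypes also gave small camera p for this list. Wild-type replicate 1 with Ts1Cje replicates 1, 2 and 4 against the rest gave 2.7e-15. Wild-type replicates 1, 2 and 4 with Ts1Cje replicate 3 gave 2.2e-10. Both keep most arrays of a genotype together, so they may carry part of a genotype difference. An even mix, wild-type replicates 1 and 3 with Ts1Cje replicates 2 and 4, gave 1.3e-08. The list's array means differed by 0.19 (exact permutation p = 0.057), wild-type replicate 1 lying above Ts1Cje replicate 3.

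Of 6 markers of ependymal cells, which line the ventricles, 5 were below 0, the median was -0.32, and 3 fell adjusted over the list alone, among them Tmem212 (-0.73, SE 0.15) and Ccdc153 (-0.51, SE 0.14); camera gave an adjusted p of 0.0089, or 0.63 with an estimated correlation, and the array means an exact permutation p of 0.057. Without wild-type replicate 2 the adjusted p was 0.051. Of 15 genes of neurogenesis and the cell cycle, 13 were below 0 with a median of -0.14. Ccnd2 stood at -0.18 (SE 0.09) and Eomes at -0.41 (SE 0.20), the latter above background on 3 of 4 Ts1Cje arrays. Camera gave this list an adjusted p of 0.033, or 0.63 with an estimated correlation. Its array means gave an exact permutation p of 0.20, Ts1Cje replicate 1 stood at -0.32 and Ts1Cje replicate 3 at 0.11, and the call was lost without Ts1Cje replicate 1 (median -0.08, adjusted p = 0.28), wild-type replicate 2 (-0.09, 0.20) or Ts1Cje replicate 4 (-0.13, 0.072) and passed in 11 of 20 alternatives. Of 60 genes of oxidative phosphorylation, 45 were below 0, with a median of -0.04 and Ndufa8 at -0.13 (SE 0.04) and Ndufa1 at -0.12 (SE 0.05), at an adjusted p of 0.014, or 0.94 with an estimated correlation, and an exact permutation p of 0.11. That call was lost without wild-type replicate 1 (adjusted p = 0.15), Ts1Cje replicate 3 (0.11) or wild-type replicate 4 (0.060), and passed in 15 of 20 alternatives. No member of these last 2 lists passed adjusted over its list alone. All 4 of these camera calls were lost with an estimated correlation.

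The remaining 26 lists did not pass with either correlation in the main setting. Of 20 alternatives with the preset correlation, copper and iron handling passed in 9, heat shock in 7 and immediate early genes in 4. Some of these used all 8 arrays. They include quantile normalization for copper and iron handling (camera adjusted p = 0.030), array weights for heat shock (0.013) and the replicate block for immediate early genes (0.027). With the preset correlation, copper and iron handling passed without wild-type replicate 1 (adjusted p = 0.026) or Ts1Cje replicate 2 (0.030), heat shock without wild-type replicate 1 (0.049), Ts1Cje replicate 2 (0.030) or wild-type replicate 3 (0.0032), and immediate early genes without Ts1Cje replicate 2 (0.0088) or wild-type replicate 3 (0.0066). Interneurons passed without wild-type replicate 3 (0.014) and cholesterol synthesis without Ts1Cje replicate 2 (0.024). Medians were 0.28 for blood, 0.10 for copper and iron handling, 0.09 for interneurons, 0.03 for striatum, thalamus and habenula, endothelium and sex-linked genes, 0.02 for microglia and for calcineurin and NFAT signalling, and 0.01 for glutamatergic synapses. They were -0.0023 for NRF2 targets, -0.0037 for the chromosome 10 and 17 counterparts of human chromosome 21 genes, -0.01 for neocortex, choroid plexus and oligodendrocyte precursors, -0.02 for the disomic flank, -0.04 for GABA synapses, -0.05 for cholesterol synthesis and myelin, -0.06 for heat shock, -0.07 for mural cells and fibroblasts, -0.08 for CA2 and CA3, -0.09 for dentate granule cells, -0.11 for astrocytes, -0.14 for immediate early genes and -0.15 for CA1. Leaving out 1 array changed the sign of 15 of these 26 medians. It moved 4 by more than 0.1: blood to 0.07 without Ts1Cje replicate 2 and 0.60 without Ts1Cje replicate 1, immediate early genes to -0.24 without wild-type replicate 3 and -0.0052 without wild-type replicate 1, choroid plexus to -0.14 without wild-type replicate 1 and 0.10 without wild-type replicate 3, and mural cells and fibroblasts to -0.17 without wild-type replicate 2 and 0.04 without Ts1Cje replicate 1. The other 22 moved by up to 0.098. By fry, no list moved one way (lowest adjusted p 0.26). Its mixed test, of change in either direction, passed for the chromosome 10 and 17 list (adjusted p = 0.00014), CA1 and dentate granule cells (0.0030 each), interferon response (0.030) and neocortex (0.033).

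**Figure D3:**
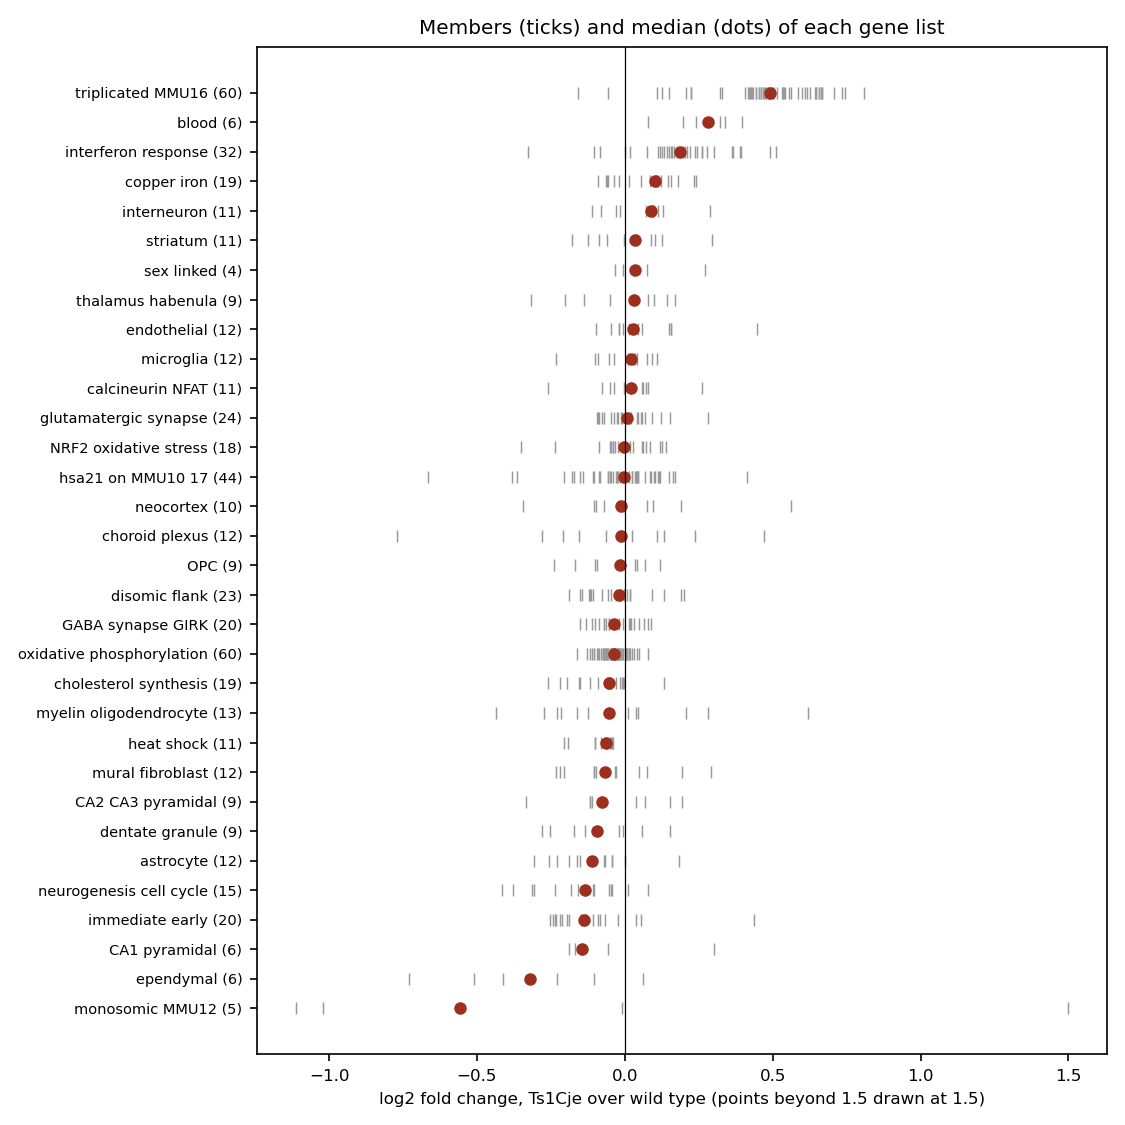
Log2 fold change of Ts1Cje over wild type (x axis) of each tested member (ticks) and the median (dots) of the 32 gene lists (rows, with the number of members tested), from 4 arrays per group; values beyond 1.5 are drawn there. The triplicated list has a median of 0.49 and the interferon-response list 0.19, the ependymal list -0.32 and the list of the deleted segment -0.56.

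The labels do not give the sex of the mice. Both probes of Xist were not well above background on any of the 8 arrays, and Ddx3y, Eif2s3y, Kdm5d and Uty were above background on all 8. The 4 Y-linked genes stood at -0.03, 0.07, 0.27 and -0.01 in that order, with adjusted p of 0.50 or more.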

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

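Of 144 sets of 4 arrays examined (named genes, list means and quality measures), 9 had 1 array far from the other 3 by Dixon's ratio, the gap over the range, where 7.2 are expected by chance. The tests of Dnah11 and of slide column, and the split counts for features outside the segments and for gene lists, were chosen after the result was seen.

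Ts1Cje replicate 1 accounts for 4 of the 9. Its spike-in slope was 0.811 against 1.08 to 1.09 on the other Ts1Cje arrays (ratio 0.958) and its spike-in R squared 0.878 against 0.990 (ratio 0.994). Its mean over the triplicated list was 0.29 against 0.22 for the others (ratio 0.924), and over the NRF2 list 0.07 against -0.04 to -0.02 (ratio 0.836). Without this array 37 features were called and the triplicated shift was 0.46. In wild type, replicate 1 stood apart for Ifnar2, at 1.29 against at most 1.13 (ratio 0.835), and replicate 2 for CA2 and CA3 markers, at 0.17 against -0.04 to -0.03 (ratio 0.950). Ts1Cje replicate 2 stood apart for Tmem196, at -4.11 against -3.85 to -3.82 (ratio 0.889), and for astrocyte markers, at -0.17 against -0.02 to -0.01 (ratio 0.891), and Ts1Cje replicate 3 for sex-linked genes, at 0.12 against 0.01 (ratio 0.921).

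The triplicated shift of 0.48 was set against a scaling difference between the groups and slide column, which follows genotype. The disomic flank, 23 genes near the segment with 2 copies in both groups, shifted by -0.0245, a far smaller size and in the other direction, which argues against scaling. The 20 tested genes just proximal to Sod1 had a median of 0.0131, single genes ranging from -0.66 to 1.01. A slide-column effect has no reason to follow the segment, which argues against it for this list. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave 47 called genes, the real one. The highest other split gave 1, which argues against chance for that count. An effect of the extra copies remains a hypothesis, tested on these data alone.

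The 9 features outside both segments were set against dissected tissue, sex and chance. The highest share of markers past the threshold among choroid plexus, thalamus, striatum and neocortex lists was 0%, but so was that of the ependymal list, whose median was -0.32, and of all 30 lists. The share therefore decides nothing, and a difference in dissected tissue stays open. The largest difference of a Y-linked gene was 0.27 (Kdm5d, adjusted p = 0.50) and Xist was not above background on any array, which argues against sex. Of 35 splits, 1 gave 9 such features and the highest other split gave 0, but calls elsewhere loosen the adjusted threshold in the real split. Adjusted over outside features alone, the real split gave 3 and the highest other 1. Among 35 splits the real one can at best rank first, and this adjustment was chosen after the data were seen. Chance is therefore not excluded for these 3, and is left open for the other 6. One of the 3 is Glycam1, near background in Ts1Cje; over probes above background on all 8 arrays the counts were 2 and 1, a narrow margin. At the unadjusted p of the weakest of the 9 calls, the highest other split gave 4. Which of the 9 hold stays open, since 1 to 6 of them passed without 1 array.

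The 125-fold rise of Dnah11, opposite to its copy number, was set against ciliated cells, a related transcript and spot artefacts. The ependymal list had a median of -0.32, which argues against more ciliated cells. Of 7 other dynein heavy chain genes tested, the highest upper 95% bound was 0.45, which argues against a signal from one of these. The lowest Ts1Cje array lay 6.51 above the highest wild-type array on the log2 scale, which argues against an artefact on 1 or 2 arrays. What stays open is that the single probe may detect a transcript joined to Dnah11 sequence by the rearrangement, or a transcript not tested here.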

How the results depend on the processing

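The slide-row block, the 2 changes to the deleted-segment list, the test of named genes only and the adjustment over outside features alone were chosen after seeing the data; the slide or scan block was not run, since there is 1 slide and 1 scan. The shift of the triplicated list kept its direction in all 22 alternatives (0.41 to 0.51) and its p of 0.0286 in 20. With the replicate block (0.48, exact sign-flip p = 0.125) and the slide-row block (0.48, exact permutation p = 0.0556) the design cannot give a smaller p, and the same holds for the deleted-segment list (0.85 in both). That list reversed to -0.67 without Dnah11 and to -0.42 as a median over members, because Dnah11 alone raises its mean. The variance prior does not enter a list mean.

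Counts of genes moved more. Higher, lower and outside both segments, they were 18, 1 and 3 at an adjusted p of 0.01 and 79, 19 and 38 at 0.1; 21, 4 and 4 with the array median as centre; 22, 1 and 3 with no filter; and 72, 17 and 28 with array weights. The lower and outside counts were 11 and 16 with normexp, 13 and 17 with quantile normalization, 8 and 15 with probes above background on all 8 arrays, 11 and 19 with the trended and robust prior, and 13 and 25 over named genes only, where fewer features are tested. The mean over probes gave 18 outside, and adjusted over outside features alone 3 passed. The cause was not tested for the others. Without 1 array in turn, higher counts were 12 to 38, lower 0 to 6, outside 1 to 9, lists passing camera 2 to 8, the triplicated shift 0.46 to 0.48 and the deleted-segment shift 0.81 to 0.91. Camera's lists were 4 in the main setting and 2 with normexp.

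With the replicate block, 1 gene was higher, 0 lower and 0 outside, and 7 lists passed camera. Deviations of same-numbered arrays correlated at 0.24, 0.19, 0.11 and 0.05. The 2 arrays of replicate 1 correlated best with each other, as did those of replicate 2. Wild-type replicate 3 and Ts1Cje replicate 4 also correlated best with the array of their own number. Wild-type replicate 4 and Ts1Cje replicate 3, however, correlated best with each other. The labels do not tie numbers to litters, so these values do not settle whether the numbers mark pairs, and the main fit used no block. Of single named genes, 35 were followed: 565 alternative values kept their side of the threshold, 113 fell short of it and 20 passed it newly. None reversed in sign with the main or the alternative value past the threshold. Sign changes with neither value past it count among the 565, as for Sp8, whose alternatives ranged from -0.23 to 0.05. Signal over background limits Macc1, Abcb5, Xist, Glycam1 and Eomes.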

Other observations

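The tests below were chosen after the results were seen. Some genes outside the naming rule, chosen after their values were seen, passed adjusted over their list alone and not over all genes. Cbs, cystathionine beta-synthase, a human chromosome 21 gene that lies outside the triplicated segment in the mouse, stood at -0.67 (adjusted p = 0.076 over all genes, 0.011 over its list). Of regional markers, Wfs1 of CA1 stood at 0.30 (0.22 and 0.011), against Fibcd1 at -0.19 (0.32 and 0.012) and Pou3f1 at -0.15 (0.51 and 0.050) of the same list, whose median was -0.15; C1ql2 of dentate granule cells at -0.25 (0.15 and 0.0075) and Rspo1, in the neocortex list, at 0.56 (0.066 and 0.0020).

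The ependymal markers below 0 led to a hypothesis that genes of motile cilia are lower in general. A list of 52 such genes without the dynein chains already seen was then written; 1 of them, Rsph1 at -0.37, is also in the chromosome 10 and 17 list. Of 42 tested, 32 were below 0, the median was -0.15, none passed over all genes or adjusted over the list alone, and array means differed by -0.14 (two-sided exact permutation p = 0.057). Camera gave p = 1.7e-05, or 0.11 with an estimated correlation. Wild-type replicate 3 lay below Ts1Cje replicate 3, so the hypothesis stays open, and the amount of ventricular lining in each dissection could give the same values.

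Because the interferon receptor chains are triplicated, the interferon-response genes may respond to the extra receptor copies. The array means give an exact permutation p of 0.057, and the list does not pass with an estimated correlation, so this stays open. Gene lists passing camera's preset correlation are also frequent in splits that mix genotypes: 19 of the 35 splits gave at least the 4 lists of the real one, and the highest other split gave 8, so chance cannot be excluded for these 4 lists. With an estimated correlation 0 lists passed.

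All 11 called features with no position were higher, with log2 fold changes of 0.48 to 0.79 and a median of 0.52, where called genes of the triplicated segment ranged from 0.41 to 0.77. Higher called features outside both segments ranged from 0.44 to 0.64, so these sizes do not tell where the 11 lie. Their direction did differ from that of the calls outside both segments, of which 4 of 9 were higher (two-sided Fisher's exact p = 0.0081). That test counts each feature as independent and does not place any single one of the 11. Their positions were not determined here.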
